A study of Drosophila melanogaster with 4 samples.

How the data were processed

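ChIP-seq libraries from white prepupae were grouped by their titles into Groucho ChIP (2 libraries) and input DNA (2 libraries). The deposited file is 1 peak list for the series in GFF3 format, with no column that belongs to a single library. Per the file headers, the coordinates are on FlyBase release 5, and the source column names MACS as the caller. The submitters' processing notes name the build BDGP5, CASAVA (versions 1.7.0.2 and 1.7.0.3), BWA and MACS2. The order of these steps, the peak threshold, read filters, and whether libraries were pooled before calling are not given in the sources used here. The score of each peak is the value of the authors' caller, as deposited. Its scale, such as a minus log p or q, is not stated, and it was used only within this list, to rank, describe, compare and correlate peaks. The list held 1644 distinct score values between 5.91 and 614.92. The narrowest peaks, 178 of them, were 201 bp wide, and no peaks overlapped. Peaks fused or divided by the caller would change both their number and their spacing, which is why joined peaks were examined as an alternative.

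Positions are 1-based, as in the file. Arm length was taken as the end of the last peak on the arm, which gave 119 Mb over the 6 main arms, and the 38 peaks on heterochromatic or unplaced sequences stayed out of the comparisons of arms, positions and spacing, but were part of the description of the list and of the correlation of score and width. Arms were compared by 10000 random draws of the peaks in proportion to arm length, two-sided, with Benjamini-Hochberg adjustment over the 6 arms. The smallest adjusted p this gave was 0.00024. Spacing was compared with 1000 random placements of the peak centres on the same arm, without forbidding overlap. Peaks with at least 4 others within 10 kb were counted. Median scores on X and on the large autosome arms were compared by 100000 permutations of the peaks. Correlations of score and width had 100000 permutations. These tests, the alternatives to them, and the rule for named sites were set before the data were examined. The rule names the 10 peaks of highest score and the 10 windows of 50 kb with the most peaks, by coordinates, where no annotation of the file's release is given.

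Peaks joined at 5 kb, windows with at least 1 peak, placement within 100 kb blocks and permutation of 1 Mb blocks were settings added after seeing the data. Other steps were added after the list had been opened. These are the 95% intervals from resampling 1 Mb blocks, the ratios by score range, the pair counts by distance (200 placements), the region around the highest peak and the numbers of empty and crowded windows. Intervals of densities and ratios had 10000 resamplings, and that of the score difference had fewer. The chains of peaks less than 5 kb apart, the peak-free stretches, the counts at arm ends and the relation of score to neighbours were also added then. Block resampling keeps neighbouring peaks together, and its intervals are therefore wider than those of single peaks. The intervals cover the unevenness along the chromosomes, not differences between libraries, and the exact Poisson interval of chromosome 4 covers counting error only.

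The gene table at hand is on assembly release 6, whereas the peaks are on release 5, and coordinates were not carried between them. Distances to transcription start sites, gene lists and sequence motifs, which had been planned, were therefore not analysed here, and no gene is named. Of the 23 other settings listed beforehand, 13 need such annotation or sequence and 10 were run. The settings run were the 50% of peaks with the highest scores, peaks less than 1 kb apart joined, covered bases in place of peak number, a wider neighbourhood (50 kb with at least 9 others) and peaks wider than the median. Calculations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and plots matplotlib 3.10.9.

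The placement and resampling steps were tested on simulated lists of 11127 peaks, 20 of each kind. Each simulated list had fewer random draws, placements and resamplings than the data, so the smallest p it could give was larger. In uniform lists, X was called in 0 and grouping in 0 of 20 lists. With X at 0.6 times the autosomal density, X was called in 20 of 20 lists with a mean ratio of 0.601, and grouping in 1. In lists with added groups of peaks, grouping was called in 20 of 20 and X in 0. The number of peaks per arm in those lists was drawn by arm length before peaks were grouped on the arm. The 0 calls of X therefore do not test whether grouping misleads the comparison of arms. The 95% block interval held the true ratio in 20 of 20 lists of each kind. Simulated groups lay at random along each arm, so the interval was not tested with blocks of 1 Mb as uneven as in the data.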

Results

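Binding of Groucho was profiled by chromatin immunoprecipitation and sequencing (ChIP-seq) in white prepupae of Drosophila melanogaster. Groucho is a co-repressor that does not bind DNA itself and is brought to chromatin by sequence-specific repressors such as Hairy. White prepupae are animals at the onset of metamorphosis, and the labels name no dissected tissue. The antibody was a rabbit polyclonal serum against a Groucho peptide, and the animals came from a strain marked with y, cn, bw and sp. The series holds 4 libraries, of which 2 are Groucho ChIP and 2 are input DNA. The processed data are 1 peak list for the series, with a position and a MACS score for each peak. The scores are the authors' own, on a scale that is not stated. The list carries no value per library, so no spread between replicates could be computed, and the read depth of the libraries is unknown. All p-values below treat the peak or the stretch of chromosome as the unit and describe this list alone. The design implies 1 comparison, Groucho ChIP against input, and the question addressed is where in the genome Groucho was enriched.

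Groucho enrichment was called at 11165 sites, and 11127 of them (99.7%) lay on the 6 main chromosome arms 2L, 2R, 3L, 3R, 4 and X. The peaks covered 6.87 Mb in total, and those on the main arms covered 5.75% of the arm length. Most sites were narrow and a small set was wide or high in score. The median width was 454 bp, with an upper quartile of 730 bp, and 282 peaks were wider than 2 kb. The median score was 18.38, with quartiles of 12.27 and 36.9, against a maximum of 614.92. The 10% of peaks with the highest scores held 40.3% of the summed score, and 760 peaks (6.81%) scored above 100. That share of the summed score depends on the scale, which is not stated. Score rose with width across the 11165 peaks (Spearman's rho = 0.776, Pearson's r = 0.664). Both correlations had the smallest p that 100000 permutations can give (1e-05, two-sided), and peaks are not independent replicates. The relation had been classed beforehand as a technical one of the caller, so it is not evidence about binding.

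The strongest Groucho site of the genome, by score, lay on 3R, from 21827784 to 21837281 (FlyBase release 5). It scored 614.92, against a median of 18.38, and was also the widest peak, at 9498 bp. Score rose with width across the list, so a rank by score does not separate strength of binding from width. This peak had 5 other peaks within 10 kb and stood in a group of high-scoring sites. Within 25 kb of it on either side, 14 peaks covered 25517 bp of a 52.4 kb span between 21808927 and 21861327, and 5 of them scored above 100. The second-highest score of that region, 358.79, belonged to a peak at 21845286 to 21848383. The next strongest sites of the genome were on 2R. A peak at 18565002 to 18566750 scored 466.72 and had 10 other peaks within 10 kb, and a peak at 19553959 to 19555059 scored 433.67 and had 4. On 3R, a distal peak at 27538050 to 27539971 scored 428.56 and had 5. The strongest site of 2L, at 14489940 to 14491367, scored 401.26 and had 9 others within 10 kb. The remaining 5 of the 10 highest peaks scored between 362.36 and 376.41 and had 4 to 9 others within 10 kb. They lay on 2R (9812747 to 9813384 and 2434408 to 2437135), 3L (13469601 to 13471836) and 2L (12002935 to 12007839 and 3579874 to 3581256). None of the 10 was on X or on chromosome 4, which held 1397 and 10 of the 11127 peaks on the main arms. With 10 peaks, this says little about either chromosome. Genes at these positions were not assigned, because no annotation of release 5 was used here.

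**Figure D1:**
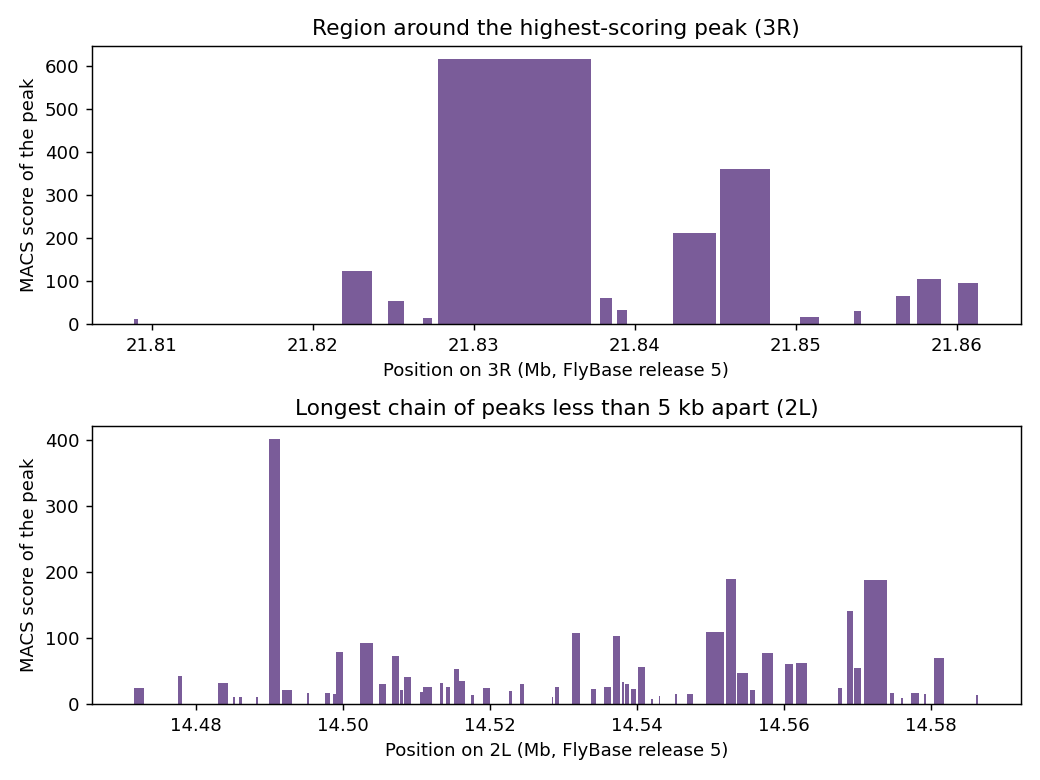
The horizontal axes give the position in Mb (FlyBase release 5) and the vertical axes the MACS score, with each peak drawn as a box from its first to its last base. The upper panel shows the 14 peaks around the highest-scoring peak on 3R (614.92), and the lower panel the 58 peaks of the longest chain of peaks less than 5 kb apart, on 2L, chosen after the positions were seen, whose highest score was 401.26.

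Groucho sites were spread unevenly over the chromosomes. The X chromosome held 1397 peaks, or 62.8 per Mb, against 101 per Mb on the 4 large autosome arms. X thus had 0.618 times the autosomal density (95% interval 0.525 to 0.72, from resampling blocks of 1 Mb). Under placement in proportion to arm length, 2074 peaks were expected on X, and the observed number was 0.673 times that (adjusted p = 0.00024, 10000 random placements of n = 11127 peaks, two-sided, Benjamini-Hochberg over 6 arms), the smallest that these placements gave. The small chromosome 4, which is largely heterochromatic, held 10 peaks where 126 were expected, or 0.0796 times as many, with the same adjusted p. That value was 0.152 after peaks less than 5 kb apart were joined and 0.427 over windows of 50 kb with at least 1 peak, of which chromosome 4 had 4. Its density was 7.42 peaks per Mb (exact Poisson 95% interval 3.56 to 13.6). The first 7 of its peaks, by position, lay between 522008 and 578170, and the strongest, at 522008 to 522665, scored 173.91.

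Among the large autosome arms, 2R had the highest density, with 110 peaks per Mb (95% block interval 92.4 to 126). The arms 3L and 3R followed with 105 (90.6 to 119) and 103 (94.4 to 112), and 2L had 86.9 (73.9 to 98.8). All 4 departed from the number expected over the 6 arms when peaks were placed singly, by 1.18, 1.13, 1.11 and 0.932 times for 2R, 3L, 3R and 2L, with adjusted p of 0.0006 for 2L and 0.00024 for the others. Single placement ignores that peaks lie in groups. With blocks of 1 Mb resampled, 2L stayed below the other 3 large autosome arms (ratio 0.82, interval 0.688 to 0.95), whereas the intervals of 2R (1.11, 0.924 to 1.3), 3L (1.05, 0.89 to 1.22) and 3R (1.02, 0.906 to 1.16) held equality. The lower number on 2L was no longer past the threshold among the 50% of peaks with the highest scores (0.953 times the expected number, adjusted p = 0.096, n = 5569 peaks), nor after peaks less than 5 kb apart were joined (0.999, adjusted p = 0.987). The higher number on 3L was also lost after that joining (1.05, adjusted p = 0.106, n = 4082 joined peaks).

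**Figure D2:**
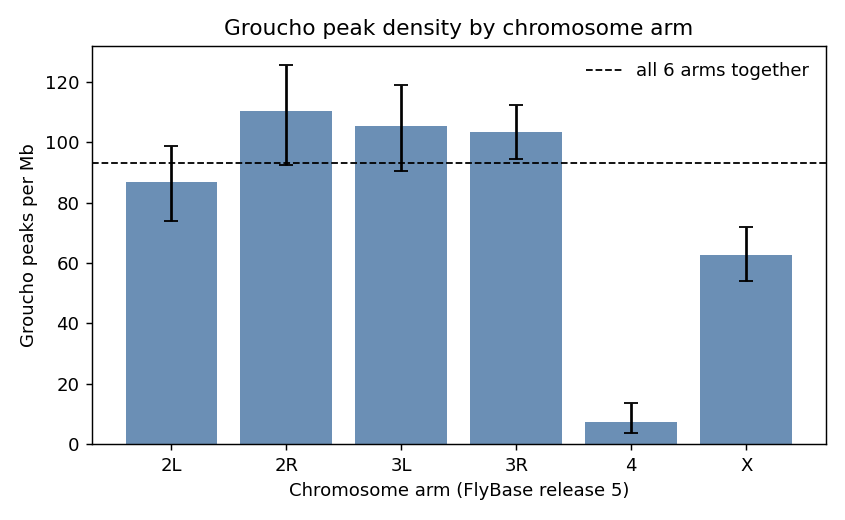
Bars give Groucho peaks per Mb (vertical axis) for each chromosome arm (horizontal axis), with arm length taken as the end of the last peak, and the dashed line is the density of all 6 arms together. Error bars are 95% intervals from resampling 1 Mb blocks, or the exact Poisson interval for chromosome 4; X, at 62.8, and chromosome 4, at 7.42, lie below the large autosome arms at 86.9 to 110.

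Peaks on X, although fewer, scored somewhat higher. Their median score was 19.85, against 18.17 on the large autosome arms, a difference of 1.68 (95% block interval 0.35 to 2.99). The difference was past the threshold when single peaks were permuted (p = 0.00143, 100000 permutations, two-sided). Among peaks wider than the median the medians were 37.36 and 34.56, and the difference of 2.8 was not past the threshold (permutation p = 0.0738). The lower number of sites on X held in each range of scores. From the lowest to the highest 25% of scores, X had 0.582, 0.552, 0.666 and 0.678 times the autosomal density, and the upper bounds of the 4 block intervals were 0.704, 0.652, 0.818 and 0.817.

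Groucho sites lay in groups. The median distance between the centres of neighbouring peaks was 3203 bp, against a mean of 7199 bp in 1000 random placements on the same arms (range 6992 to 7424). Of the 11127 peaks, 5464 (49.1%) had at least 4 others within 10 kb, whereas random placement gave 1528 on average (13.7%) and 1741 at most, a ratio of 3.58. Both differences had the smallest two-sided p that 1000 placements can give (0.002). The ratio was 12.3 among the 50% of peaks with the highest scores, where random placement of fewer peaks gave 98.5 on average, while the median distance was 0.456 times that of random placement, against 0.445 for all peaks. The ratio of peak numbers was 2.44 after peaks less than 1 kb apart were joined, 1.23 for at least 9 others within 50 kb, and 1.5 against placements that kept each peak in its own block of 100 kb. In each of these settings the observed number stayed above that of all 1000 placements.

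The excess of close pairs fell with distance. Pairs of peaks 0.5 to 1 kb apart were 2.74 times as frequent as in random placements, and pairs 1 to 2 kb apart 2.83 times. The ratio was 1.83 at 5 to 10 kb, 1.37 at 20 to 50 kb, 1.18 at 50 to 100 kb and 1.08 at 100 to 200 kb. At 500 to 1000 kb it was 1.03, where the 200 random placements ranged from 0.993 to 1.01. Pairs 0.25 to 0.5 kb apart were fewer than in any random placement (ratio 0.796), where peak width itself limits the distance.

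**Figure D3:**
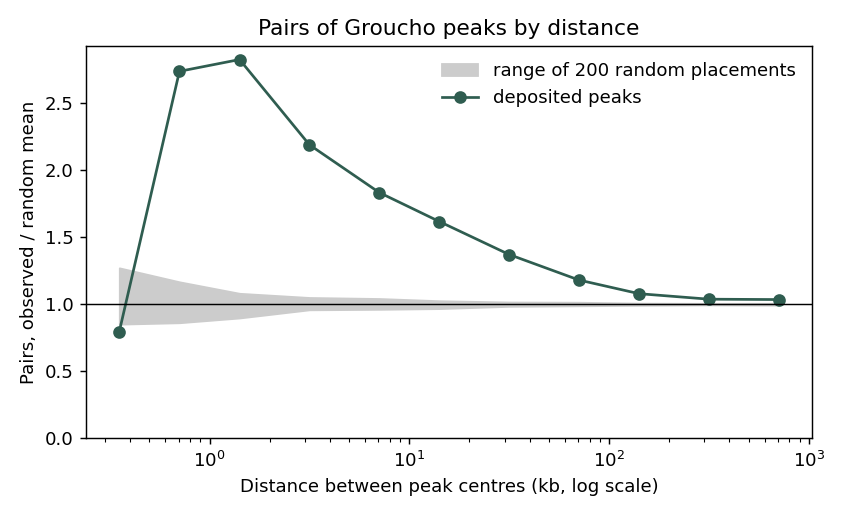
The horizontal axis gives the distance between 2 peak centres in kb on a log scale, and the vertical axis the number of such pairs divided by the mean of 200 random placements on the same arms, whose range is shaded. The ratio is highest at 1 to 2 kb, at 2.83, and declines to 1.03 at 500 to 1000 kb.

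The most densely bound stretches were named by counting peaks in fixed windows of 50 kb. The window at 17950001 to 18000000 on 3L held 31 peaks, which covered 45.2% of its length. The window at 14500001 to 14550000 on 2L and that at 2400001 to 2450000 on 2R held 29 each. The latter contained 1 of the 10 highest peaks, with a score of 363.66. A further 3L window, 16150001 to 16200000, held 28 peaks. The windows 8650001 to 8700000 on 3L and 14200001 to 14250000 on 2R held 26 each and had the largest covered shares of the 10 densest windows, 58.3% and 55.1%. The list of 10 was completed by 750001 to 800000 on 3L (25 peaks), 500001 to 550000 and 3550001 to 3600000 on 2L (24 each) and 5750001 to 5800000 on 3R (23 peaks). In 1000 random placements no window held more than 22 peaks. Of the 2391 windows, 89 held 15 or more peaks, against at most 4 in any placement, and they contained 14.9% of the peaks. At the other extreme, 491 windows (20.5%) held no peak, whereas random placement left 52.8 empty on average and 71 at most. On X, 70.9% of the windows held a peak, and on the large autosome arms 82.4%. Windows with a peak held 4.42 peaks on average on X and 6.15 on the large autosome arms.

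**Figure D4:**
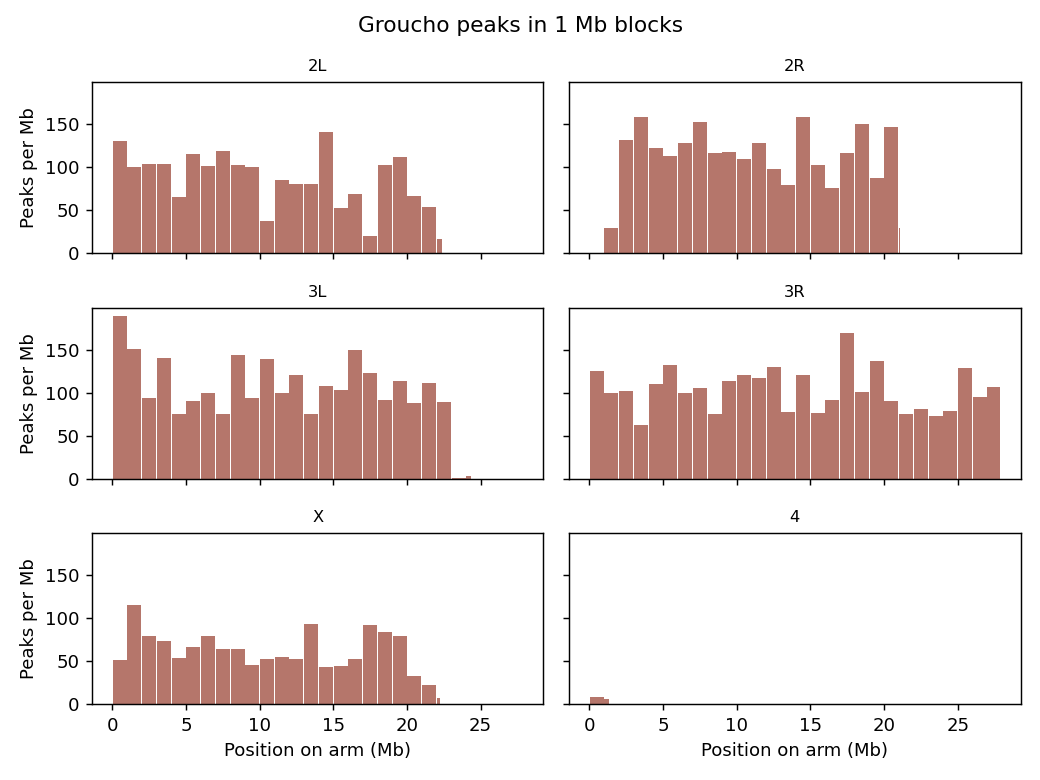
Each panel is a chromosome arm, with the position in Mb on the horizontal axis and Groucho peaks per Mb, counted in blocks of 1 Mb, on the vertical axis. The first block of 2R holds 1 peak, the last full block of 3L and its shorter final block hold 1 each, and the panels of X and chromosome 4 lie lowest.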

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

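The use of the score as a test of copy number on X, and the tests of peaks joined at 5 kb, of windows with a peak, and of placement within 100 kb blocks were chosen after the peak list had been seen.

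A signal outside the main arms drew attention. The list holds 38 peaks on heterochromatic or unplaced sequences of release 5, which the comparisons of arms, positions and spacing left out. Of these, 21 were on Uextra, 8 on U and 9 on the heterochromatic parts of chromosomes 2 and 3. Their median score was 15.4, and the highest, 84.93, lay on Uextra at 562094 to 562474.

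The lower density of Groucho sites on X is not all accounted for by splitting of autosomal regions into peaks less than 5 kb apart. The ratio was 0.784 (0.687 to 0.886) after such peaks were joined. A lower copy number or read depth of X stays open: the median X score was 1.68 higher than the autosomal one (95% block interval 0.35 to 2.99), but it covers called peaks only, so the bound that a higher median speaks against lower depth was wrong. X had 0.582 and 0.552 times the autosomal density in the lower score ranges and 0.666 and 0.678 times in the higher ones, and a loss of weak peaks could give that order, which was not tested. Wholly empty windows of 50 kb are not the whole cause, because windows with a peak held 0.719 times as many peaks on X (0.644 to 0.797). Shorter peak-free sequence stays inside such windows, so peak-free sequence as such stays open. This holds although a bound was met that had been set after the list, but before this value, was seen. GC content, mappability and gene density were not analysed here, and no biological explanation was tested.

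For the grouping of peaks, splitting of broad regions into peaks less than 1 kb apart does not account for the whole. After joining, 804 peaks still had at least 4 others within 10 kb, against 235 to 429 in 1000 unjoined random placements. Splitting across wider gaps was not tested for the grouping. Joining removes close neighbours whatever the cause, so a part for splitting stays open. Differences between fixed blocks of 100 kb do not account for all of the grouping. The 5464 peaks compare with 3477 to 3829 when each peak is placed within its own block. A rich stretch that crosses a block border is spread over both blocks by that placement. Stretches of about 100 kb are therefore not excluded as the whole cause. Placement within blocks raised the mean number from 1528 to 3648 and lowered the ratio from 3.58 to 1.5. Rich and poor stretches of 100 kb or more may thus account for part of the grouping. A dense group smaller than 100 kb also raises the mean of its own block, however. Uneven mappability below that scale was not analysed here, and no biological explanation was tested, because the design has 1 stage and 1 strain.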

How the results depend on the processing

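Peaks joined at 5 kb, windows with a peak, placement within 100 kb blocks and permutation of 1 Mb blocks were chosen after seeing the data. Of 40 alternatives with a test, 35 kept the direction and the side of the threshold, and 0 reversed. The number of peaks was 5582 among the 50% with the highest scores and 7497 after joining at 1 kb. The lower number on 2L was no longer past the threshold among those peaks (0.953 times the expected number), after joining at 1 kb (0.954) or after joining at 5 kb (0.999, adjusted p = 0.987, n = 4082). The higher number on 3L was no longer so after joining at 5 kb (1.05, adjusted p = 0.106, n = 4082), where fewer peaks were tested. The X minus autosome score difference was 2.8 among peaks wider than the median (p = 0.0738, permutation test), and the cause was not tested. The number on X stayed at 0.647 to 0.825 times the expected one, and that on chromosome 4 at 0.0873 to 0.427. The ratio for peaks with many neighbours was 12.3, 2.44, 1.23 and 1.5 with the 50% of highest scores, joining at 1 kb, the 50 kb neighbourhood and 100 kb blocks, and the median distance was 0.445 to 0.658 times the random one. No paired analysis was possible because the peak list holds no value per library. Leaving out a replicate was impossible for the same reason, and 13 settings that need an annotation or sequence of release 5 were not run. Read depth is unknown, so a stretch without a peak is one where none was called, not one shown to lack Groucho.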

Other observations

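All tests and counts in this part were chosen after the peak list had been seen. Joining peaks less than 5 kb apart gave 4082 chains on the main arms, of which 1859 were single peaks. At the other extreme, 132 chains of 10 or more peaks held 18% of all peaks in 3.1% of the arm length. The longest lay on 2L at 14471617 to 14586409, spanned 115 kb and held 58 peaks, with a highest score of 401.26. Next by peak number came 3L at 17940378 to 18010037 with 42 peaks, 3R at 17405856 to 17486434 with 40, 2R at 7356892 to 7441571 with 37 and 3L at 8644364 to 8713709 with 37. The chain at 14189950 to 14245773 on 2R had the largest covered share of the 10 longest by peak number, 67.9% of 55.8 kb, and the highest median score, 41.4. Of these chains 9 were on X and 123 on the large autosome arms, or 0.404 and 1.28 per Mb, and chains form less often at the lower peak density of X, which this comparison does not take into account. Chromosome 4 had 0 of them, at a length that would hold few.

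The arm ends next to the centromere were poor in Groucho sites on 4 of the 5 large arms. The 1 Mb at the centromere end of the arm sequence held 1 peak on 2R, 2 on 3L, 13 on X and 27 on 2L. The middle of those arms held 115, 106, 65.8 and 87.7 peaks per Mb. On 2L, 3L and X this 1 Mb was counted back from the last peak, not from the end of the sequence. On 3R the 1 Mb at that end held 125 peaks, and the first peak of the arm began at base 100. The separate heterochromatic sequences were not part of these counts. Between neighbouring peaks, the longest peak-free stretch, 1200 kb, ran from 371393 to 1571174 on 2R, and 2 stretches of 811 and 609 kb followed at the end of 3L. Away from the centromeres, a stretch of 401.1 kb on 3L, from 13496446 to 13897583, and one of 354 kb on 2L, from 16889369 to 17243068, held no peak. In 1000 random placements the longest distance between neighbouring centres reached 146 kb on 3L, 172 kb on 2L and 130 kb on 2R, so the stretches named here exceeded every placement on their arm. On chromosome 4 the longest stretch between 2 peaks, 506 kb, lay within the placements, which reached 799 kb, and the sequence before its first peak, at 522008, was not part of this comparison. Without the first block and the last 2 blocks of each arm, X still had 0.641 times the autosomal density (0.553 to 0.736).

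Score and crowding were weakly related. Peaks with no other within 10 kb had a median score of 16.95, and those with 8 or more had 21.37. Peaks scoring above 100 made up 4.08% of the former and 9.71% of the latter. Spearman's rho across 11127 peaks was 0.0783 (p = 1e-05, the smallest that 100000 permutations within arms can give). With peaks less than 1 kb apart joined, rho was 0.0417 (permutation p = 0.0003), below the highest permuted rho of 0.0455. A bound set before this value was seen, but after the rho of 0.0783 was seen, that rho should exceed the highest permuted one, was not met, which by that bound counts for the splitting of broad regions by the caller as the cause. The small p cannot decide whether splitting is the whole cause, because the permutation treats peaks as independent although nearby peaks share neighbours. The bound was judged too lenient only after the result was seen, and joined peaks also carry the highest score of their members, so splitting may be part of the cause, and its part cannot be told apart from a relation of score to crowding. Neighbouring peaks resembled each other in score when less than 0.5 kb apart (rank correlation 0.117, adjusted p = 6e-05 over 6 distance ranges, permutation test). The correlation was 0.00976 at 0.5 to 1 kb and 0.0244 at 1 to 5 kb, neither past the threshold, and 0.0494 at 5 to 20 kb (adjusted p = 0.0301). At 20 to 100 kb it was -0.0267 and above 100 kb 0.0797, neither past the threshold.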
